A study of Arabidopsis thaliana with 24 samples.

How the data were processed

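The samples were tips of the main root of Arabidopsis thaliana seedlings at 6 days, in 2 genotypes and 2 treatments. The genotypes were the Columbia wild type (WT) and brl3-2, a line with a T-DNA insertion in BRL3, which encodes a brassinosteroid receptor of the BRI1 family. Seedlings were kept for 2 h in liquid medium with DMSO (mock) or with zeocin, an antibiotic of the bleomycin family that breaks DNA. The labels disagree on the dose: the sample characteristics and the series design give 10 µM and the treatment protocol gives 2 µM, so no dose is attached to the results. The labels describe 3 biological replicates for each of the 4 groups, which makes 12 libraries, and each library was sequenced in 2 runs, which makes 24 described samples. Per the labels' protocols, RNA was extracted on a Maxwell RSC instrument, had an integrity number above 7, and was made into libraries with the TruSeq Stranded mRNA kit.

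The authors deposited a single table of raw read counts per gene, with 1 column per library. Per the submitters' processing notes, the tools were FastQC 0.11.2, Trimmomatic 0.38, HISAT2 2.1, featureCounts 1.6.2 and edgeR 3.34.1, and the genome build was TAIR10. Their settings are not given in the sources used here, including whether featureCounts used strand and whether the reads of the 2 runs were added. Of the 33297 rows of the table, 1 has no gene name. It was left out of library sizes and tests and held at most 0.0039% of a library's count. The other 33296 rows carry locus identifiers, of which 33011 matched the TAIR10.1 gene table that supplied symbols, products, coordinates and strands.

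Total counts were 32668516 to 38276389 in 10 libraries and 70212858 and 73481046 in the WT mock and WT zeocin libraries numbered 3. No gene count was read in any library for 8036 genes. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 7.81 to 99.6 over the genes compared), so all 12 were kept as separate replicates. Intervals and floors given for counts cover counting error only.

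Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough reads were kept with filterByExpr (minimum count 10, minimum total 15), which left 19437 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries, so that the 4 groups shared 1 estimate of the spread. The contrasts were zeocin against mock in each genotype, brl3-2 against WT in each treatment, and the difference between the 2 zeocin responses (interaction). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The adjusted p given for a gene is from this two-sided test. Levels are CPM values, that is counts relative to the library total with TMM scaling. Where a group had no read of a gene, the fold change is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 reads the ratio of counts is given with its 95% counting interval.

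Before the data were examined, 21 gene lists with 233 entries at 231 loci were written down, together with the tests, the alternatives and the rule for naming genes. The lists were DNA damage response, damage sensing and end joining, S phase and replication, G2/M cell cycle, brassinosteroid biosynthesis, brassinosteroid receptors and signalling, brassinosteroid-responsive genes, root stem cell niche, xylem, phloem, root hair and epidermis, endodermis, root cap, photosynthesis in the shoot, heat shock, touch with wounding and jasmonate, hypoxia, developmental cell death, and auxin-responsive, cytokinin-responsive and abscisic acid genes. XTH22 and MYB56 were each in 2 lists. For 6 entries the TAIR10.1 table uses another name, read here as a name of the same gene, and for 5 it gives no name. The rule set down beforehand left out an entry where symbol and locus disagreed. These entries were not counted as disagreeing, and all were kept by locus. Of the 231 loci 211 were tested and 20 had too few reads. Each list was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 21 lists of a contrast. The adjusted p given for a list is from this test unless another is named.

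Genes were named by a fixed rule: BRL3, then up to 10 genes with the largest rise and 10 with the largest fall among those called, with at least 1 CPM in the higher group and no overlap between the libraries of the 2 groups, then up to 4 members of each list with the smallest adjusted p. Values of 1 member of the DNA damage list are not reported here, though it is counted in the list. Other members of the DNA damage list, MCM2, ESM1, members of the photosynthesis list and of gene families, and AT2G08735 in mock, AT1G06963 and AT3G00560 were named after their values were seen. Exons of each named gene were compared with exons on the opposite strand in TAIR10.1. Where strand was not used in counting, reads over such a shared stretch cannot be assigned to either gene.

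The alternatives were size factors by the RLE method, no filter on low counts, DESeq2 1.42.0, limma-voom, a further minimum of a 2-fold change, a fit on only the groups compared, a replicate block, leaving out each library in turn, and, for lists, camera with an estimated correlation and limma's fry. For the correlation of the 2 responses, subsets of genes were also used. Leaving out both WT libraries numbered 3 was added after the data were seen. Using only 1 sequencing run had been planned and was not run, since the table has 1 column per library.

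The tests were checked on simulated counts for all 19437 genes with 200 genes changed. For zeocin against mock in WT, 40.3% of 1.5-fold, 77.6% of 2-fold and 93.9% of 4-fold changes were recovered, with 6 of 19217 unchanged genes called. For the interaction the shares were 17.9%, 49.3% and 87.9%, with 7 of 19217 unchanged genes called. Camera called the raised list and 0 of 20 unchanged lists in both simulations. Genes were drawn independently of each other, so these simulations do not test camera on lists whose genes vary together. Changing 200 genes at once makes the Benjamini-Hochberg threshold easier to pass than where few genes differ. The shares recovered are therefore likely too high for a gene that differs among few others.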

Results

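RNA-seq counts were available for 12 libraries of root tips, 3 for each combination of genotype (WT or brl3-2) and treatment (mock or zeocin). Library totals ranged from 32668516 to 38276389 counts, except for 70212858 in WT mock replicate 3 and 73481046 in WT zeocin replicate 3. The first principal component of the log2 CPM values held 50.4% of the variance and separated the 6 zeocin libraries from the 6 mock libraries. The second held 15.3% of the variance and placed WT mock replicate 3 at −41.8 and WT zeocin replicate 3 at −24.1, while the other WT libraries lay above 0. Of the mutant libraries, brl3-2 mock replicate 3 lay lowest, at −20.6, and the others lay between −9.64 and 14.4. Changes below are log2 fold changes ± SE with 3 libraries per group. Each SE is the change divided by the square root of the test's F statistic, and intervals of changes are built on it. For genes with few reads in a group this SE can be smaller than counting error alone. Examples are AT1G75945 in mock, with 4 counts in WT, and AT2G08735 under zeocin, with 5 counts in WT.

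**Figure D1:**
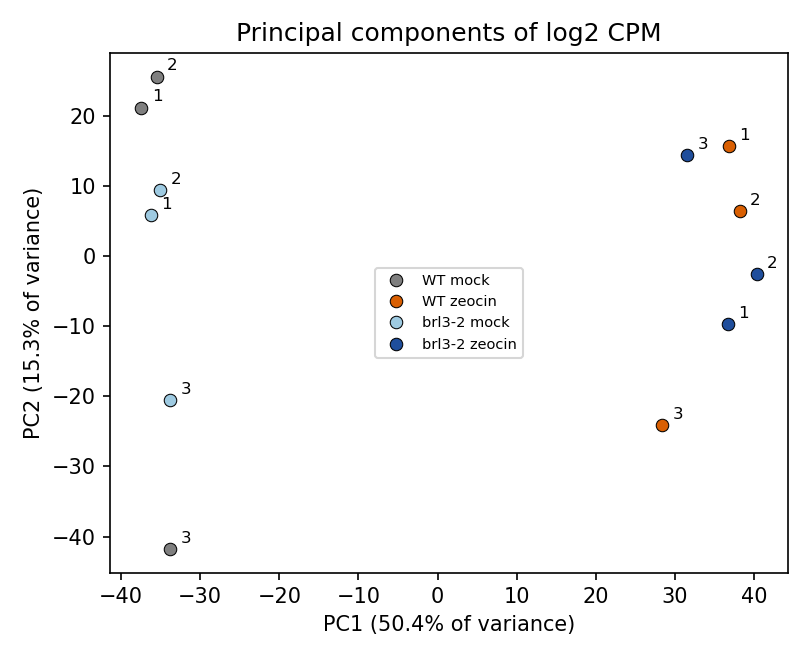
Principal components of log2 CPM for the 12 libraries, with PC1 on the horizontal and PC2 on the vertical axis, one point per library and its replicate number beside it. Zeocin and mock libraries lie on opposite sides of PC1, and the WT libraries numbered 3 lie apart from the other WT libraries on PC2.

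The BRL3 transcript was examined first, since the mutant line carries an insertion in this gene. BRL3 (AT3G13380, chromosome 3, bases 4346330 to 4350939 in TAIR10.1) stood at 10.9 ± 1.73 CPM (SD, n = 3) in WT mock root tips and at 1.00 ± 0.285 CPM in brl3-2 mock root tips, which is 10.9-fold lower (log2 −3.45 ± 0.22, edgeR adjusted p = 4.8e-05). Under zeocin it stood at 28.1 ± 5.75 CPM in WT and 1.00 ± 0.063 CPM in brl3-2, which is 28.1-fold lower (log2 −4.81 ± 0.23, edgeR adjusted p = 2.8e-06). All 6 mutant libraries lay between 0.698 and 1.26 CPM, and all 6 WT libraries between 9.55 and 31.7 CPM. In WT, BRL3 itself rose 2.56-fold with zeocin (log2 1.36 ± 0.18, edgeR adjusted p = 0.00052). In brl3-2 the change was −0.01 ± 0.26, with a 95% interval of −0.58 to 0.57. The difference between the 2 responses was −1.37 ± 0.32 (95% interval −2.06 to −0.67), and over all genes tested its edgeR adjusted p was 1.0.

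**Figure D2:**
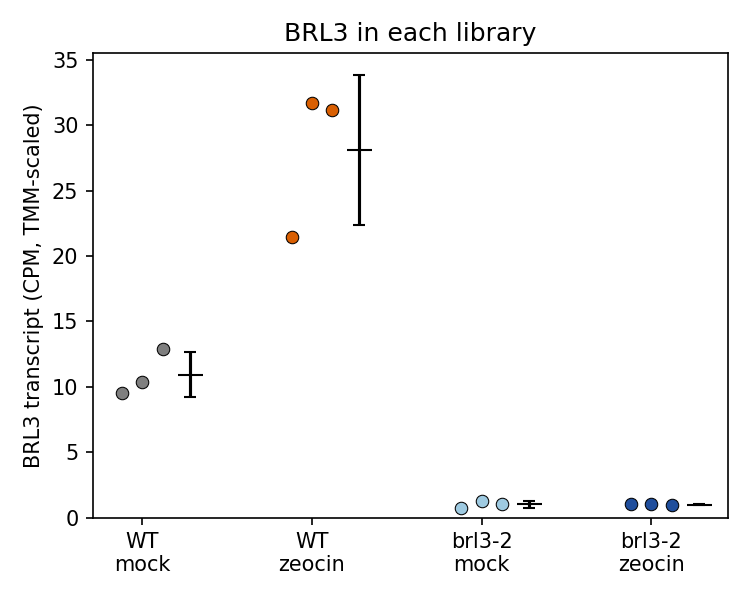
BRL3 level in each library, in CPM with TMM scaling, by genotype and treatment. Points are libraries and the lines beside them the mean ± SD of 3, with the WT groups at 10.9 and 28.1 CPM and both mutant groups at 1.00 CPM.

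The comparison of zeocin with mock in WT asks which transcripts change in root tips within 2 h of exposure to a DNA-damaging agent. Genes of the DNA damage response rose together, and 22 of the 26 tested members of that list passed the test, by up to 9.02 on the log2 scale. SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, went from 0.306 ± 0.022 to 160 ± 9.05 CPM (SD, n = 3; log2 9.02 ± 0.19), and SMR4 (AT5G02220) of the same family rose by 5.44 ± 0.14. XRI1 (AT5G48720), a transcript known to be induced by X-rays, rose by 4.80 ± 0.10 to 741 ± 34.6 CPM, and RAD17 (AT5G66130), part of a checkpoint clamp loader, by 2.96 ± 0.07. BRCA1, a gene of homologous recombination, was among them at 5.53 ± 0.21. So were the ribonucleotide reductase subunit gene TSO2 at 6.32 ± 0.17, the poly(ADP-ribose) polymerase gene PARP2 at 5.09 ± 0.14 and the checkpoint kinase gene WEE1 at 1.32 ± 0.11.

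Over the whole transcriptome 967 of 19437 genes were called, of which 792 rose and 175 fell, and 395 and 63 of these changed at least 2-fold. Leaving out 1 library at a time gave 579 to 1059 rises and 93 to 340 falls, and the fit on only the groups compared 487 and 79. Every zeocin library lay on one side of every mock library for 16.2% of genes, where chance gives 10%. Among the 10 largest rises, 6 genes had no read in WT mock. AT4G25330, annotated as a SAWADEE protein, was at least 482-fold higher, OZS1 (AT1G12480), the anion channel gene also called SLAC1, at least 332-fold, and the helicase gene AT1G20750 at least 229-fold. SK9 (AT3G21850), a SKP1-like gene with close relatives that could share its reads, was at least 212-fold higher, the receptor kinase gene CRK6 (AT4G23140) at least 171-fold, and AT3G28510 at least 121-fold. AT4G05380 was higher by a count ratio of 1428 (395 to 11795), and the uncharacterised AT4G09215 and AT5G07165 rose by 11.61 ± 0.23 and 11.29 ± 0.27. Of the 10 largest falls, UMAMIT14 (AT2G39510), an amino acid exporter gene, fell by 4.82 on the log2 scale (SE 0.30), from 6.59 ± 1.12 to 0.233 ± 0.066 CPM (SD, n = 3). UMAMIT17 (AT4G08300) of the same family changed by −2.50 ± 0.36, AT4G00910, annotated as a malate transporter, by −2.81 ± 0.24, and OCT1 (AT1G73220), an organic cation transporter gene, by −2.41 ± 0.47. The others were AT5G10580 (−2.65 ± 0.19), AT2G28780 (−2.54 ± 0.43), AT2G47560 (−2.43 ± 0.47), the transcription factor genes MYB78 (−2.28 ± 0.33) and MYB48 (−2.16 ± 0.20), and AT2G18560 (−2.09 ± 0.32). Exons on the opposite strand cover 43.0% of the exon bases of OZS1, 43.1% of AT4G00910, 31.1% of AT2G47560 and 11.1% of AT5G10580.

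Of the 21 lists, 4 passed in WT. The DNA damage response had a median of 3.51 (adjusted p = 1.2e-60; 22 members rose adjusted over the list alone), and it alone held with an estimated correlation, at adjusted p = 0.016. In the S phase and replication list 5 of 17 genes rose, and 7 adjusted over the list alone (median 0.21, adjusted p = 2.0e-07; adjusted p = 0.40 with an estimated correlation). They were RNR1, the other ribonucleotide reductase subunit gene, at 2.61 ± 0.15, the chromatin assembly gene FAS1 at 0.40 ± 0.08, the sliding clamp gene PCNA1 at 0.53 ± 0.13, and the helicase subunit genes MCM3 at 0.48 ± 0.12 and MCM2 at 0.40 ± 0.10. In the list of touch, wounding and jasmonate 3 of 11 genes rose, and 4 adjusted over the list alone (median 0.61, adjusted p = 5.0e-04; adjusted p = 0.40 with an estimated correlation): the cell wall enzyme gene XTH22 (3.22 ± 0.27) and the transcription factor genes WRKY33 (1.32 ± 0.16) and ZAT12 (0.86 ± 0.22). The root stem cell niche list lay lower as a set, with a median of −0.19 (adjusted p = 0.040; adjusted p = 0.40 with an estimated correlation), while 0 of its 12 genes passed on their own, also adjusted over the list alone. WOX5, the marker of the quiescent centre, was at −0.57 ± 0.32.

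The other 17 lists did not pass in WT (adjusted p = 0.112 to 0.927). In 7 of them a member rose or fell. Of 11 genes of damage sensing and end joining, the replication protein gene RPA1A rose (0.95 ± 0.06; 1 adjusted over the list alone), while the kinase genes ATM and ATR and the regulator SOG1 were at −0.08 ± 0.14, 0.04 ± 0.11 and 0.04 ± 0.06. Of 26 G2/M genes, CYCA1;1 rose (1.15 ± 0.16; 1 adjusted over the list alone), whereas the mitotic cyclin gene CYCB1;1 (AT4G37490), a known reporter of DNA damage in the damage list, rose by 3.58 ± 0.14. In the phloem list the sieve element genes SEOR1 (1.62 ± 0.17) and CALS7 (0.51 ± 0.08) rose among 6 (2 rose and 1 fell adjusted over the list alone). Among 10 auxin-responsive genes IAA29 (4.26 ± 0.19) and IAA5 rose, IAA5 by a count ratio of 29.4 (7.77 to 248), and IAA2 (−0.54 ± 0.10) and LBD16 (−1.12 ± 0.23) fell (3 and 3 adjusted over the list alone). The brassinosteroid enzyme gene ROT3 (−0.41 ± 0.10) fell among 8 biosynthesis genes (1 rose and 2 fell adjusted over the list alone), and HRE1 (−0.53 ± 0.11) among 12 hypoxia genes (1 rose and 3 fell adjusted over the list alone). XTH22 was also the 1 gene to rise among 6 brassinosteroid-responsive genes (1 adjusted over the list alone). No member passed among 9 brassinosteroid receptor and signalling genes (1 rose adjusted over the list alone), 8 root hair genes (1 rose and 1 fell) or 6 abscisic acid genes (1 fell). None passed either way in the lists of xylem (6 genes), endodermis (7), root cap (4), photosynthesis (7), heat shock (6), developmental cell death (10) and cytokinin (5). Median, mean and test differed in sign for the G2/M, brassinosteroid-responsive, root hair and auxin lists.

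Some of these calls were lost when 1 library was left out, which also lowers power. The changes of these genes kept their sign (range over the 6 fits beside each). The niche list lost its call without WT mock 1, WT mock 2 or WT zeocin 3 (adjusted p up to 0.22), with the replicate number as a block (0.057) and in fry (0.18). So did PCNA1 (0.44 to 0.66) and MCM3 (0.39 to 0.62) without WT mock 2, WT mock 3, WT zeocin 1 or WT zeocin 2 (up to 0.16), and ROT3 (−0.48 to −0.33) without WT mock 1, WT mock 3, WT zeocin 1 or WT zeocin 2 (up to 0.17). ZAT12 (0.71 to 0.98) lost it without any library but WT mock 3 (up to 0.18), HRE1 (−0.68 to −0.45) without WT zeocin 1 or WT zeocin 2 (up to 0.063), and FAS1 (0.36 to 0.46), LBD16 (−1.37 to −0.90) and AT2G47560 (−2.78 to −1.94) without WT zeocin 2 (0.056, 0.056 and 0.051). With both WT libraries numbered 3 left out, 1133 genes were called, 834 of the 967 remained, the heat shock list passed as well, lower under zeocin (adjusted p = 0.028), and OCT1 (0.058), ROT3 (0.052) and ZAT12 (0.11) did not. In the fit on only the groups compared PCNA1, FAS1, MCM3, IAA2, LBD16, ROT3, HRE1 and AT2G47560 lost their calls (up to 0.21). So did PCNA1 and ZAT12 with the block (up to 0.085), these and MCM3 in limma-voom (up to 0.056) and ZAT12 with RLE factors (0.054). Some genes not called in the main fit passed in an alternative. In WT, GL2 (0.36, adjusted p = 0.0040) and GOLS1 (−1.23, 0.013) passed in edgeR with the block. BRI1 (0.23 and 0.24) passed in DESeq2 (adjusted p = 0.0040) and limma-voom (0.0499). The same happened for other named genes in both genotypes.

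The same comparison in brl3-2 asks how root tips of the mutant respond. Here too 22 of the 26 DNA damage response genes rose, by up to 8.71 on the log2 scale. SMR7 went from 0.436 ± 0.090 to 184 ± 34.5 CPM (SD, n = 3; log2 8.71 ± 0.19), SMR4 rose by 5.83 ± 0.15, XRI1 by 5.09 ± 0.10 to 913 ± 34.7 CPM, and RAD17 by 3.21 ± 0.07. BRCA1 was at 5.70 ± 0.21, TSO2 at 6.11 ± 0.17, PARP2 at 5.08 ± 0.14 and CYCB1;1 (AT4G37490) at 3.74 ± 0.14. In both genotypes the 4 members that did not pass were TEB, LIG6, BARD1 and FAN1, at 0.07 to 0.20 in WT and 0.07 to 0.16 in brl3-2.

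In brl3-2 1045 genes were called, of which 840 rose and 205 fell, 420 and 72 of them at least 2-fold (606 to 821 rises and 100 to 157 falls with 1 library left out, 894 and 324 in the fit on only the groups compared), and groups lay apart for 4591 of 19437 genes, where chance gives 10%. AT4G25330 was at least 384-fold higher than in mock, SK9 at least 80.5-fold, the zinc finger gene AT3G29340 at least 64.9-fold, AT3G28510 at least 56.1-fold and AT5G53240 at least 37.0-fold. Count ratios were 2145 (385 to 84751) for AT4G05380 and 545 (97.5 to 21572) for AT1G20750, and AT4G09215 and AT5G07165 rose by 10.56 ± 0.22 and 10.41 ± 0.26. Falls were again led by UMAMIT14, at −5.13 ± 0.34, followed by AT2G28780 (−3.09 ± 0.45), AT4G00910 (−2.89 ± 0.25), AT5G10580 (−2.76 ± 0.20), the peroxidase gene AT1G49570 (−2.71 ± 0.49) and OCT1 (−2.71 ± 0.50). The list ended with UMAMIT17 (−2.67 ± 0.37), the sugar transporter gene SWEET11 (AT3G48740; −2.47 ± 0.62), the terpene synthase gene TPS13 (AT4G13300; −2.39 ± 0.30) and AT1G30760 (−2.28 ± 0.36). Opposite-strand exons cover 15.6% of the exon bases of TPS13.

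In brl3-2 5 lists passed. The DNA damage response had a median of 3.78 (adjusted p = 2.0e-57; adjusted p = 0.019 with an estimated correlation; 22 rose adjusted over the list alone). With NAC085, which had 3 counts in WT mock and 2 in brl3-2 mock, at the lower end of its counting interval the median was 3.64 here and 3.51 in WT. Of the S phase list 3 of 17 genes rose, and 6 adjusted over the list alone (median 0.25, adjusted p = 1.7e-07; adjusted p = 0.37 with an estimated correlation): RNR1 at 2.82 ± 0.15, PCNA1 at 0.60 ± 0.13 and MCM3 at 0.54 ± 0.12. Touch, wounding and jasmonate genes had 2 of 11 members up, XTH22 (from 14.6 ± 3.18 to 164 ± 10.3 CPM, SD, n = 3) and WRKY33 (from 29.8 ± 2.27 to 68.5 ± 9.18 CPM), as also adjusted over the list alone (median 0.78, adjusted p = 8.7e-04; adjusted p = 0.44 with an estimated correlation). The root stem cell niche list was lower (median −0.23, adjusted p = 0.0029; adjusted p = 0.37 with an estimated correlation), and 2 of its 12 genes fell, both also adjusted over the list alone: WOX5 (−1.36 ± 0.35) and JKD (−0.25 ± 0.06), a regulator of ground tissue patterning. Brassinosteroid biosynthesis genes were lower as a set (median −0.24, adjusted p = 0.045; adjusted p = 0.37 with an estimated correlation), and of 8 members ROT3 fell (−0.55 ± 0.10; 1 rose and 1 fell adjusted over the list alone). The other 16 lists did not pass (adjusted p = 0.11 to 0.948), and in 7 of them a member was called. RPA1A (1.08 ± 0.06), CYCA1;1 (from 3.94 ± 0.822 to 8.44 ± 0.395 CPM), XTH22, the phloem genes SEOR1 (1.17 ± 0.17) and CALS7 (0.36 ± 0.08), GL2 (0.38 ± 0.10), which specifies hairless epidermis, IAA29 (4.31 ± 0.19) and IAA5 rose, IAA5 by a count ratio of 9.41 (2.92 to 48.3). LBD16 (−1.14 ± 0.24), HRE1 (−0.54 ± 0.11) and the cysteine oxidase gene PCO1 (−1.43 ± 0.37) fell. Adjusted over the list alone, the counts for rises and falls were 1 and 0 in damage sensing, G2/M and brassinosteroid-responsive genes, 2 and 0 in phloem, 1 and 1 in root hair, 3 and 3 in auxin and 0 and 2 in hypoxia. They were 1 and 2 in brassinosteroid receptors and signalling, 0 and 2 in photosynthesis, 0 and 1 in heat shock, and 0 in xylem, endodermis, root cap, developmental cell death, cytokinin and abscisic acid genes. Median, mean and test differed in sign for the G2/M and auxin lists.

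The photosynthesis list, fixed as a marker of shoot tissue, summed to 256 CPM in brl3-2 mock replicate 2 against 25.2 to 54.4 CPM in the other 11 libraries, and its median in this comparison was −2.45 (adjusted p = 0.39). Here too several calls were lost with 1 library left out, while the changes of these genes kept their sign. The biosynthesis list lost its call without brl3-2 mock 1, brl3-2 mock 3, brl3-2 zeocin 1 or brl3-2 zeocin 2 (adjusted p up to 0.14). So did SWEET11 (−2.95 to −2.22) and PCO1 (−1.68 to −1.24) without any of the 6 libraries (up to 0.17 and 0.19), WOX5 (−1.55 to −1.20) without any but brl3-2 mock 2 (up to 0.19) and JKD (−0.31 to −0.21) without any but brl3-2 mock 3 (up to 0.21). CALS7 (0.32 to 0.42) lost it without any library but brl3-2 mock 3 (up to 0.14), IAA5 without any but brl3-2 zeocin 3 (up to 0.097), and GL2 (0.30 to 0.47) without brl3-2 mock 1, brl3-2 mock 2, brl3-2 zeocin 1 or brl3-2 zeocin 3 (up to 0.20). The same held for PCNA1 (0.53 to 0.68) without brl3-2 mock 1, brl3-2 mock 2, brl3-2 zeocin 2 or brl3-2 zeocin 3 (up to 0.085), MCM3 (0.50 to 0.57) without brl3-2 mock 1, brl3-2 mock 2 or brl3-2 zeocin 2 (up to 0.080), LBD16 (−1.24 to −0.98) without brl3-2 mock 2, brl3-2 mock 3 or brl3-2 zeocin 3 (up to 0.065) and HRE1 (−0.59 to −0.49) without brl3-2 zeocin 2 (0.054). GL2, WOX5, JKD and PCO1 also lost it with no filter on low counts (up to 0.072), and these and SWEET11 in limma-voom (up to 0.084). So did GL2 and JKD in the fit on only the groups compared (up to 0.080), JKD and PCO1 with the block (up to 0.068) and GL2 with RLE factors (0.056).

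**Figure D3:**
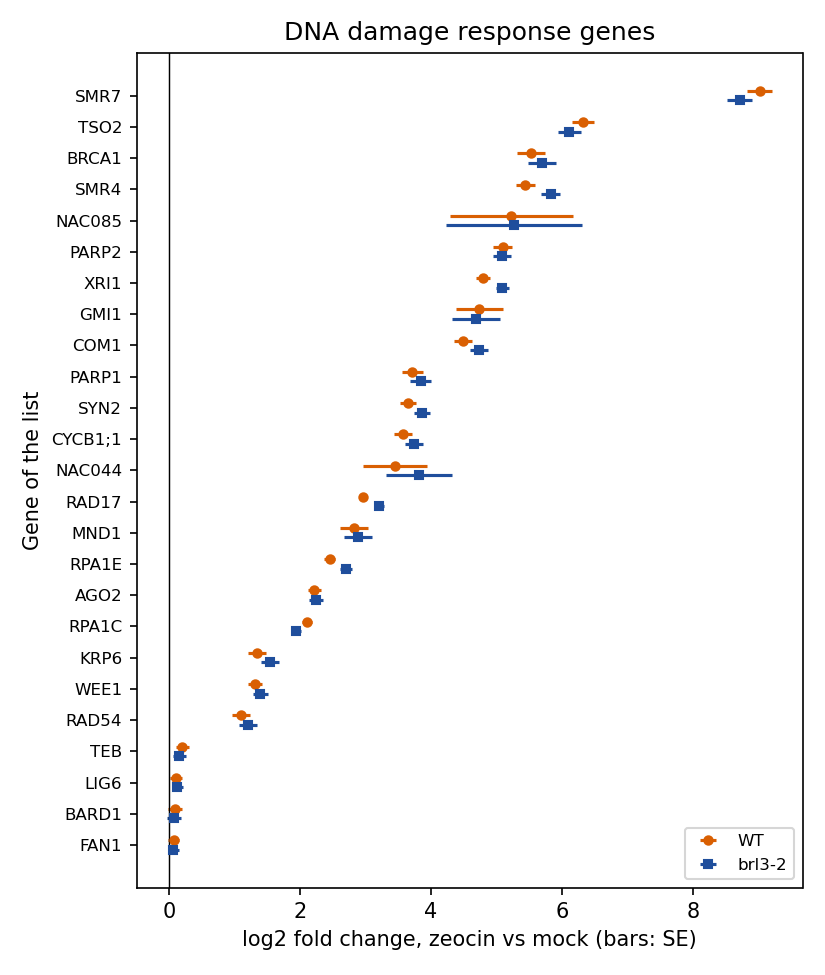
Log2 fold change of zeocin against mock for 25 of the 26 tested genes of the DNA damage response list, in WT (circles) and brl3-2 (squares), with bars for the SE. In both genotypes 21 of the genes shown lie above 1 and reach 9.02 in WT and 8.71 in brl3-2, and TEB, LIG6, BARD1 and FAN1 lie near 0.

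Whether loss of BRL3 alters the response to zeocin was tested as the difference between the 2 responses. For the 26 DNA damage response genes this difference was −0.30 to 0.39 on the log2 scale, above 0 for 18 of them, and the 95% interval of the difference lay within 1 of 0 for 22 of 26. Both genotypes shared 694 of the genes that rose, where 34.2 would be shared by independent lists, and 121 of those that fell, where 1.85 would be, while 0 genes were called in opposite directions. The 2 comparisons share no libraries. Across the 1197 genes called in either genotype 99.2% changed in the same direction, with a correlation of 0.973 and a slope of brl3-2 on WT of 0.94. Across all 19437 genes 71.4% did, the correlation was 0.893 (0.385 with no filter on low counts) and the slope 0.90. Genes are not independent replicates, so these describe the 2 profiles.

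In edgeR 0 genes passed for the difference, with 194 at an unadjusted p under 0.05, which is fewer than the 5% chance gives, and DESeq2 and limma-voom also called 0. This shortfall depended on WT mock 3. Without it 884 of 19597 genes had an unadjusted p under 0.05, and with both WT libraries numbered 3 left out 540 of 19575. In each of these fits 0 genes passed. A missed threshold does not show equal responses: the 95% interval of the difference lay within 2-fold for 80.0% of all genes and for 78.1% of those called in either genotype. The smallest p values belonged to ESM1 (AT3G14210), at −2.04 ± 0.42, and BRL3. None of the 21 lists passed (adjusted p = 0.068 to 0.967), and 0 of their 211 genes did, also adjusted over each list alone. The lowest was the DNA damage response, with a median difference of 0.10 and adjusted p = 0.98 with an estimated correlation. Median, mean and test differed in sign for the G2/M, brassinosteroid-responsive, touch and hypoxia lists. The DNA damage list passed when WT mock 3 (adjusted p = 0.0060), WT zeocin 1 (0.019), WT zeocin 2 (0.0011), brl3-2 mock 2 (0.039) or brl3-2 zeocin 3 (1.1e-06) was left out, and with the replicate number as a block (0.0031). Over all its alternatives its adjusted p ranged from 1.1e-06 to 0.985, so whether this list responds more strongly in brl3-2 depends on the libraries and the model used. The photosynthesis list passed, lower in brl3-2, without brl3-2 mock 1 (0.0011) or brl3-2 mock 3 (3.7e-05), both of which leave brl3-2 mock 2 with its 256 CPM. Developmental cell death passed, lower, without brl3-2 mock 1 (0.030), xylem without WT zeocin 1 (0.049) and root hair without WT zeocin 2 (0.013).

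**Figure D4:**
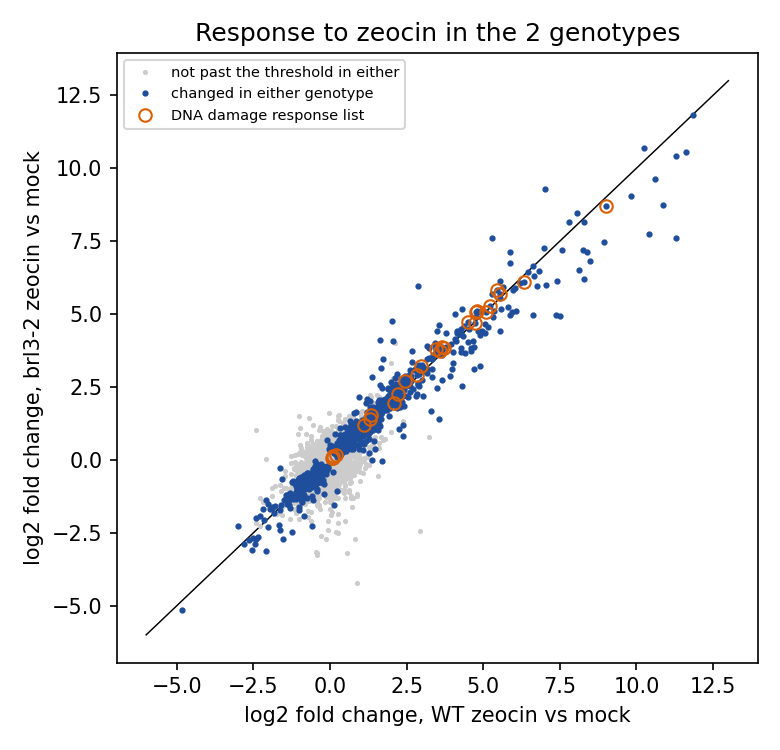
Log2 fold change with zeocin in WT (horizontal) and brl3-2 (vertical), one point per tested gene, with genes called in either genotype in blue, members of the DNA damage response list circled in orange and the line of equal change in black. The called genes follow the line, with a correlation of 0.973 across 1197 genes.

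The comparison of brl3-2 with WT under mock asks what the mutation changes in undamaged root tips, and besides BRL3 4 genes were called, all higher in the mutant. AT1G75945, an uncharacterised gene on chromosome 1 (28515245 to 28515916), stood at 0.033 ± 0.020 CPM in WT and 4.60 ± 0.987 CPM in brl3-2 (SD, n = 3; log2 7.15 ± 0.43, edgeR adjusted p = 4.8e-05). AT3G29140 on chromosome 3 (11105746 to 11106144) was higher by 2.58 ± 0.24 (adjusted p = 0.0020), and the noncoding AT1G06963 on chromosome 1 (13501086 to 13502283) by 2.95 ± 0.32 (adjusted p = 0.0052), a call lost without WT mock 1 (0.057) or WT mock 3 (0.077), and without both WT libraries numbered 3 (0.13). In the fit on only the groups compared AT3G29140 (0.066), AT2G08735 (0.066) and AT1G06963 (0.40) did not pass. AT2G08735, a noncoding RNA gene on chromosome 2 (14907257 to 14907716), was higher by a count ratio of 38.4 (12.7 to 190; adjusted p = 0.0051) at 0.839 ± 0.055 CPM in brl3-2 and was named after its values were seen. In all 771 genes had an unadjusted p under 0.05, which is fewer than the 5% chance gives. Groups lay apart for 7.72% of genes, where chance gives 10%. The count of 771 depended on the WT libraries numbered 3. It was 2226 of 19597 genes without WT mock 3 and 2489 of 19575 with both left out, each above the 5% chance gives. In each of these fits 4 genes passed, BRL3 among them, and the cause of the higher counts was not tested.

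As sets, 4 lists lay higher in brl3-2 under mock, although none of their members passed: S phase (median 0.12, adjusted p = 9.0e-04), G2/M (0.04, 0.015), xylem (0.23, 0.015) and root hair (0.40, 9.0e-04). With an estimated correlation none of them held (adjusted p = 0.63 for each). The other 17 had adjusted p = 0.098 to 0.872, and 2 genes, both of photosynthesis, passed adjusted over the list alone. Median, mean and test differed in sign for the damage sensing, brassinosteroid-responsive, niche and endodermis lists. In WT mock replicate 3 and WT zeocin replicate 3, compared as 1 set, S phase genes (8 of 17 called lower, median −0.28) and G2/M genes (1 of 26, median −0.13) lay lower than in the other WT libraries. Neither list passed with an estimated correlation (adjusted p = 0.49 for each). The raised photosynthesis genes were those of brl3-2 mock replicate 2. S phase lost its call without WT mock 3 (0.34), G2/M without WT mock 3 or brl3-2 mock 2 (up to 0.73), and xylem without WT mock 2 or brl3-2 mock 3 (up to 0.18), while root hair kept it in each (0.0012 to 0.023). With both WT libraries numbered 3 left out root hair alone of the 4 passed (0.0048), beside endodermis, higher (0.012), and heat shock, lower (0.045). The number of lists called went from 4 to 7 without brl3-2 mock 3 and to 9 without WT mock 1.

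Under zeocin the same comparison called 8 genes, 5 higher and 3 lower in brl3-2. AT1G75945 (count ratio 208, 70.8 to 1013; adjusted p = 2.3e-05), AT2G08735 (5.46 ± 0.48, adjusted p = 8.2e-04) and AT3G29140 (2.26 ± 0.24, adjusted p = 0.0055) were again higher. AT1G06963 (2.69 ± 0.32, adjusted p = 0.012) and AT3G00560 on chromosome 3 (11104610 to 11105261; count ratio 75.6, 13 to 3036; adjusted p = 0.031), both below 1 CPM, were higher too and were named after their values were seen. Besides BRL3, AT5G35940, a mannose-binding lectin gene on chromosome 5 (14090574 to 14093007), fell from 111 ± 33.7 CPM in WT to 25.0 ± 2.98 CPM in brl3-2 (SD, n = 3; log2 −2.15 ± 0.30, edgeR adjusted p = 0.037). The noncoding AT4G04223 on chromosome 4 (2036511 to 2037816) was lower by −1.61 ± 0.22 (adjusted p = 0.031). Under mock AT5G35940 and AT4G04223 were at −1.54 ± 0.29 and −1.49 ± 0.22, AT3G00560 had a count ratio of 44.7 (7.49 to 1819), and none passed (adjusted p = 0.46, 0.073 and 0.16), and the difference between treatments did not pass for any gene. Leaving out any 1 of the 6 libraries ended the calls of AT5G35940 (log2 −2.29 to −1.87, adjusted p up to 0.34), AT4G04223 (−1.79 to −1.43, up to 0.21) and AT1G06963 (2.54 to 2.80, up to 0.16), and any but brl3-2 zeocin 1 also that of AT3G00560 (up to 0.41). AT5G35940 and AT4G04223 also lost their calls with the block (0.15 and 0.12). AT3G29140 and AT4G04223 lost theirs in the fit on only the groups compared (0.14 and 0.38), where AT3G00560 had too few reads to be tested. Without both WT libraries numbered 3 AT3G29140 (0.051), AT4G04223 (0.22), AT1G06963 (0.22) and AT3G00560 (0.74) did not pass. In all 412 genes had an unadjusted p under 0.05, which is fewer than the 5% chance gives. Groups lay apart for 7.52% of genes, where chance gives 10%.

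In this comparison 4 lists lay higher in brl3-2 with no member passing, also adjusted over the list alone: the DNA damage response (median 0.19, adjusted p = 1.9e-08), S phase (0.13, 1.6e-06), G2/M (0.06, 0.0052) and root cap (0.19, 0.049). None of them held with an estimated correlation (adjusted p = 0.62 for each), and the other 17 had adjusted p = 0.112 to 0.980. Median, mean and test differed in sign for the lists of brassinosteroid biosynthesis, brassinosteroid receptors, phloem, hypoxia, developmental cell death, auxin and cytokinin. WT zeocin replicate 3, compared together with WT mock replicate 3, also had lower DNA damage response genes than the other WT libraries (8 of 26 called lower, median −0.20, adjusted p = 6.4e-04). The list did not pass with an estimated correlation (adjusted p = 0.49). Without WT zeocin 3 S phase (0.13) and G2/M (up to 0.26, also without brl3-2 zeocin 3) lost their calls and 2 lists were called. Root cap lost it without any library but brl3-2 zeocin 2 (up to 0.24), and the DNA damage list kept it in each (2.7e-17 to 0.012). Summed over the DNA damage list, brl3-2 zeocin 1, 2 and 3 stood at 7068, 7012 and 5526 CPM. WT zeocin 1, 2 and 3 stood at 5838, 6037 and 5472 CPM. The sum of brl3-2 zeocin 3 thus lay below those of WT zeocin 1 and 2, so the groups overlapped. With both WT libraries numbered 3 left out, only the DNA damage list passed (adjusted p = 0.015) and 4 genes did.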

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

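The tests of a batch shared by the libraries numbered 3, of mature tissue, of opposite-strand overlap for genes without reads and of linkage to BRL3 were chosen after the results they concern had been seen. The tests of depth and of opposite-strand overlap for the genes that differ between genotypes were set down before.

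Whether BRL3 responds differently to zeocin in the 2 genotypes is not settled. It rose by 1.36 on the log2 scale in WT and changed by −0.01 in brl3-2, a difference of −1.37 (95% interval −2.06 to −0.67) that excludes 0 for this gene taken alone, although its edgeR adjusted p over all genes was 1.0. With about 1.00 CPM in both mutant groups, the mutant value rests on 102 and 104 counts over 3 libraries each.

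The WT mock and WT zeocin libraries numbered 3 stood apart from the other WT libraries, with 2802 genes that differed (1643 higher and 1159 lower). Depth, as the number of reads alone, is argued against as the whole cause. After both libraries were thinned to the median total of the other WT libraries 2625 genes still differed, 2395 of them shared. Thinning keeps relative levels, so it cannot test why these 2 columns hold more counts, such as the adding of both runs. A batch shared by all 4 libraries numbered 3 cannot be told apart from other causes: the deviations of these 2 correlated at 0.59 with each other and at 0.40 and 0.42 with those of brl3-2 mock 3, but at −0.32 and −0.12 with those of brl3-2 zeocin 3, a single library. A larger share of mature tissue cannot be told apart from other causes, because S phase (median −0.28, adjusted p = 5.2e-05) and G2/M genes (median −0.13, adjusted p = 0.024) were lower and endodermis genes higher (7 of 7, median 0.77, adjusted p = 0.0021), and xylem (6 of 6 higher, median 0.22, adjusted p = 0.21) and root hair genes (6 of 8 higher, median 0.46, adjusted p = 0.14) lay higher without passing, whereas phloem genes lay lower without passing (0 of 6 higher, median −0.34, adjusted p = 0.10). With an estimated correlation none of these 6 lists passed (adjusted p = 0.65 for xylem and 0.49 for the others). A batch of these 2 libraries, alone or with brl3-2 mock 3, stays open too, and no biological explanation other than the share of mature tissue was tested.

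SMR5, a known DNA damage gene, and MYC2, a jasmonate regulator, had 0 counts in all 12 libraries, as did PARP3 and PRE1. Opposite-strand exons cover 100% of the exon bases of SMR5 and 98.5% of those of MYC2. Among 338 protein-coding genes wholly covered in this way 95.3% were at 0, against 15.5% of those with no overlap. Among 6058 genes covered in part, which include MYC2, 8.57% were at 0. A candidate explanation for SMR5 is therefore that reads over gene models on both strands were assigned to neither. For MYC2 the same may hold, but genes covered nearly in full were not counted apart from those covered less. The 0 counts of both are therefore not read as absence of expression. For PARP3 and PRE1 such overlap is argued against, since 0% of their exon bases are covered in the TAIR10.1 gene models, which may differ from those used in counting.

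Besides BRL3, 7 genes differed between brl3-2 and WT in at least one treatment. None, 0 of 7, lies within 1 Mb of BRL3, the nearest being 6.75 Mb away, which argues against linkage to the insertion as their common cause. Reads from an opposite-strand gene are argued against too, since 0 of 7 share exon bases with one. AT3G00560 and AT3G29140 lie 484 bases apart and were both higher in brl3-2. An effect of the loss of BRL3 and other differences between the 2 lines, such as further insertions, stay open and were not tested.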

How the results depend on the processing

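Leaving out both WT libraries numbered 3 was chosen after the data were seen, and the other alternatives before. Of 468 results for named genes, 92 were past the threshold and 63 of these stayed past it under every alternative run, and 0 called values changed sign (a change of sign in a gene called in neither fit is not counted). BRL3 kept its direction and call in all alternatives run for its rise in WT (log2 1.27 to 1.52) and for both genotype comparisons (−3.65 to −3.24 and −4.97 to −4.72), and it was −3.45 in mock under RLE factors, DESeq2 and the block alike. The counts of genes past the threshold stayed within 1.5 times under RLE factors, no filter, DESeq2 and limma-voom, except that DESeq2 called 12 genes for brl3-2 against WT in mock. In DESeq2 this and other counts held more falls, and the cause was not tested.

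Requiring a 2-fold change by construction lowered the zeocin counts to 458 in WT and 492 in brl3-2. Fits on only the groups compared, with fewer libraries for the spread, gave 566 genes for zeocin in WT but 1218 in brl3-2, and 2 in the mock genotype comparison and 5 in the zeocin genotype comparison. With an estimated correlation camera called 1 list in WT, 1 in brl3-2, 0 in the mock and 0 in the zeocin genotype comparison, while fry, which tests lists against no change rather than against other genes, called 4, 6, 0 and 0. The auxin list was among its calls in WT and brl3-2 (adjusted p = 0.011 and 0.015), though not among those of camera, and the niche list was not among its calls in WT (0.18). Without both WT libraries numbered 3, the zeocin genotype comparison had 4 genes and 1 list and the response correlation was 0.852. That correlation was 0.385 with no filter, 0.973 over called genes and 0.955 over genes of at least 10 CPM, and the cause was not tested.

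Leaving out 1 library at a time gave 673 to 1399 genes and 3 to 4 lists for zeocin in WT, and 706 to 973 genes and 4 to 5 lists in brl3-2. For the difference of the responses it gave 0 genes in each case and 0 to 2 lists. The genotype comparison had 4 to 5 genes and 4 to 9 lists in mock, and 4 to 5 genes and 2 to 6 lists under zeocin, and the response correlation was 0.836 to 0.879 (jackknife SE 0.036). With fewer libraries each of these fits has less power, yet WT zeocin rose to 1399 genes without WT mock 3.

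With the replicate number as a block the counts of genes were 1041, 1144, 0, 6 and 6 in the order of the comparisons above, and the lists 3, 5, 1, 6 and 5, where the 1 list for the difference was the DNA damage response (adjusted p = 0.0031). The main fit had no block, as set down before the data were examined. Of 18 same-numbered pairs, 9 deviated together at over 0.1 (range −0.32 to 0.59). For 8 of 12 libraries the closest library of another group had the same number. This share is larger than that of same-numbered libraries among all libraries of other groups. Batches shared by same-numbered libraries are therefore not excluded. Values from the first or second sequencing run alone could not be had from a table with 1 column per library. At this depth and replication a simulated 2-fold difference between responses was called in 49.3% of genes, so smaller differences than that were often not detectable. The simulation held no libraries that stand apart, as the WT libraries numbered 3 do, so the share in the real data may differ.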

Other observations

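The families below, chosen from the products of all genes tested, were examined after the results were seen, as was the largest library value of the photosynthesis list. The counts over other splits of the libraries were planned.

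Among the 121 genes that fell with zeocin in both genotypes, a few families had more members than expected. A family here is the genes that share a product phrase, which misses members described otherwise, such as LBD16. Of 270 families with at least 10 tested genes, each tested for rises and for falls (540 one-sided Fisher's exact tests with Benjamini-Hochberg adjustment), 4 passed for falls and 0 for rises. The UMAMIT or MtN21 family of amino acid and metabolite transporters had 5 of 35 members among the 121 genes, where 0.218 would be expected (adjusted p = 0.0013): SIAR1, UMAMIT11, UMAMIT14, UMAMIT17 and UMAMIT20. In WT SIAR1 was at −1.35 ± 0.17 and UMAMIT11 at −1.95 ± 0.15, and in brl3-2 at −1.56 ± 0.17 and −1.70 ± 0.15. MYB transcription factor genes had 5 of 67 (MYB20, MYB34, MYB43, MYB48 and MYB78; adjusted p = 0.012), genes described as LOB domain-containing 3 of 13 (LBD14, LBD33 and LBD39; adjusted p = 0.012) and bHLH genes 5 of 80 (adjusted p = 0.019). With camera and an estimated correlation the unadjusted p for the families in WT and brl3-2 was 0.055 and 0.067 for UMAMIT, 0.61 and 0.86 for MYB, 0.0046 and 0.013 for LOB domain-containing, and 0.11 and 0.16 for bHLH genes. Among rises the lowest values belonged to heavy metal transport genes (6 of 32, adjusted p = 0.090), NAC genes (7 of 52, adjusted p = 0.21) and WRKY genes (6 of 43, adjusted p = 0.27).

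In brl3-2 mock replicate 2 the photosynthesis genes stood at 256 CPM in sum. LHCB1.3 was at 124 CPM against 2.46 to 12.4 CPM in the other 11 libraries and RBCS1A at 33.7 CPM against 0.50 to 3.54 CPM, and both have close relatives that could share reads, for which no value was tested beyond the list's 256 CPM against at most 54.4 CPM elsewhere.

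For each comparison of 3 libraries with 3, the 6 libraries can be split in 10 ways, which are too few for a share under 0.05. The real split gave 967 genes for zeocin in WT, 1045 for zeocin in brl3-2, 5 for genotype in mock and 8 for genotype under zeocin, and the highest of the other splits gave 0 in each, so that 1 of 10 splits was as large. For the difference of the responses, the real split gave 0 genes, so that 60 of 60 drawn splits had to give at least as many and the count says nothing about chance. The highest of the others gave 25 genes, which may point to a structure of the samples beyond the groups, and no cause was tested.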
